A study of Chlorella sorokiniana with 6 samples.

How the data were processed

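Messenger RNA was sequenced from cells of Chlorella sorokiniana strain KMN3, a unicellular freshwater green alga grown in BBM medium. Cells were placed in sterile distilled water for irradiation and were sampled 24 h after it, per the labels. The labels describe 6 libraries in 3 groups: 2 without irradiation, 2 after UV at 1 J/cm2 and 2 after gamma rays at 1 kGy. The table holds columns for 5 of them. UV replicate 2 was not analysed here, so the UV group consisted of a single library.

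The deposited table gives raw counts per assembled transcript, one column per library, with no normalization. Per the submitters' processing notes, fastp 0.20.1 and featureCounts 2.0.1 were used. Paired-end libraries were made from enriched mRNA with a NEBNext Ultra II kit, per the labels' protocols. Every ID has the form that the de novo assembler Trinity gives its transcripts, in which the last part numbers the isoform within a cluster of related sequences, called a locus here. The assembly settings, the aligner, the strand setting and the handling of reads that match several transcripts are not given in the sources used here. Transcripts of one locus can share sequence, so the authors' counting could split or repeat reads between them, and a count of a single isoform is uncertain for that reason. Low counts were more often even than odd: between 69.9% and 77.2% of the counts from 1 to 9 in a library were even, and 2 was more frequent than 1 in each of the 5 libraries. Counting both mates of a pair would give such counts, which was not tested; if so, counts are not independent molecules and counting intervals are too narrow.

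The files do not pair the transcript IDs with gene names, and no genome or annotation was used here. The 25 gene lists fixed before the data were examined (among them DNA repair, fatty acid synthesis, triacylglycerol assembly, photosystems, antioxidant enzymes and nitrogen assimilation) match on gene or product names, so none of them was applied, and the planned list tests (camera, fry) were not run. For the same reason the rule for named genes was used in the form fixed for unnamed IDs: per comparison, the 2 transcripts with the largest rise and the 2 with the largest fall among those with an adjusted p under 0.05, a mean abundance of at least 3 log2 CPM (counts scaled to the library size) over the libraries, and all libraries of one group above all of the other.

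The table holds 121410 transcripts in 97773 loci, of which 88254 hold 1 transcript, and 6490 transcripts had 0 counts in all libraries. Counts summed to 18075627 and 15194358 in the control libraries, 12707113 in the UV library, and 13164018 and 14293834 in the gamma libraries. A floor of 3 counts corresponds to 0.18 to 0.258 CPM per library, and floors and intervals cover counting error only. Replicate libraries were not copies of each other: over tested transcripts with at least 20 counts summed over a pair, chi-square per degree of freedom was 13.6 for the control pair and 23.8 for the gamma pair. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

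Differential abundance was tested with edgeR 4.0.16 (R 4.3.3): filterByExpr, TMM scaling, estimateDisp, glmQLFit with default settings and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. All 5 libraries entered 1 fit of 3 groups with 2 residual degrees of freedom and a prior of 16.8, so the single UV library was assumed to vary like the others. As UV had 1 library, the filter asked for sufficient counts in 1 library only and left 27711 transcripts. It removed 93699 transcripts, which held 0.665% to 1.14% of a library's counts. Standard errors are the log2 fold change divided by the square root of F. Fold changes of transcripts at 0 in a whole group depend on the prior count, and for these a lower bound at 3 counts per library is given instead. CPM values are TMM-scaled. Log2 CPM for correlations and plots used a prior of 2 counts.

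Alternatives fixed in advance were the replicate number as a block, RLE and upper quartile scaling, no filter or at least 10 CPM in 2 libraries, DESeq2 1.42.0, only the groups compared, a 2-fold minimum, an adjusted p under 0.01 for shared calls, and each library left out in turn. edgeR's earlier quasi-likelihood method, also planned, is the default of the installed version and so is the test used. Its newer method, library totals without a scaling factor, a filter for 2 libraries and counts summed per locus were added after the data were seen.

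The test was tested on simulated data: counts for the 27711 transcripts were drawn from their means, dispersions and library sizes, and 200 were changed in 1 group, 50 at each size. For gamma against control, 5 of 50 changes of 2-fold, 29 of 50 of 4-fold, 30 of 50 of 8-fold and 40 of 50 of 16-fold were recovered, with 12 unchanged transcripts among 116 calls. For UV against control, with its 1 library, 1 of 50 changes of 2-fold, 14 of 50 of 4-fold, 35 of 50 of 8-fold and 35 of 50 of 16-fold were recovered, with 8 unchanged transcripts among 93 calls. Above 3 log2 CPM, 8-fold and 16-fold changes were recovered without exception in both comparisons. Chance values for comparisons with shared controls came from 20 simulated sets of unchanged groups over the 27711 transcripts.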

Results

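The series asks how the mRNA profile of Chlorella sorokiniana changes 24 h after UV or gamma irradiation, in the setting of lipid accumulation. Counts per assembled transcript were compared between 2 control libraries, 1 UV library (1 J/cm2) and 2 gamma libraries (1 kGy), with 12707113 to 18075627 counts per library. Transcripts are given by assembly ID, because the files do not pair these with gene names, and no pathway could be assigned. Libraries of one group were closest to each other: across the 27711 transcripts tested, Pearson's r of log2 CPM was 0.951 between the control libraries and 0.947 between the gamma libraries. The UV library lay nearer to the controls (r = 0.932 and 0.936) than to the gamma libraries (r = 0.919 and 0.911), and the control and gamma libraries were farthest apart (r = 0.898 to 0.900). These are correlations across transcripts within libraries, and transcripts are not independent replicates.

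The most abundant transcripts took a smaller part of the gamma libraries. The top 10 transcripts of each library held 9.0% ± 0.07 of its counts in controls (SD, n = 2), 9.13% in the UV library and 6.14% ± 0.21 in gamma libraries (SD, n = 2). The top 100 held 30.1% ± 0.65, 30.7% and 24.0% ± 0.40, and the top 1000 held 68.9% ± 0.10, 68.9% and 63.2% ± 0.20, in the same order. In all 3 cases the gap between control and gamma was many times the spread within either pair, but 2 against 2 libraries cannot give a two-sided exact p under 0.333. For shares of the single UV library, 95% Clopper-Pearson intervals reached at most 0.026 percentage points to either side.

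**Figure D1:**
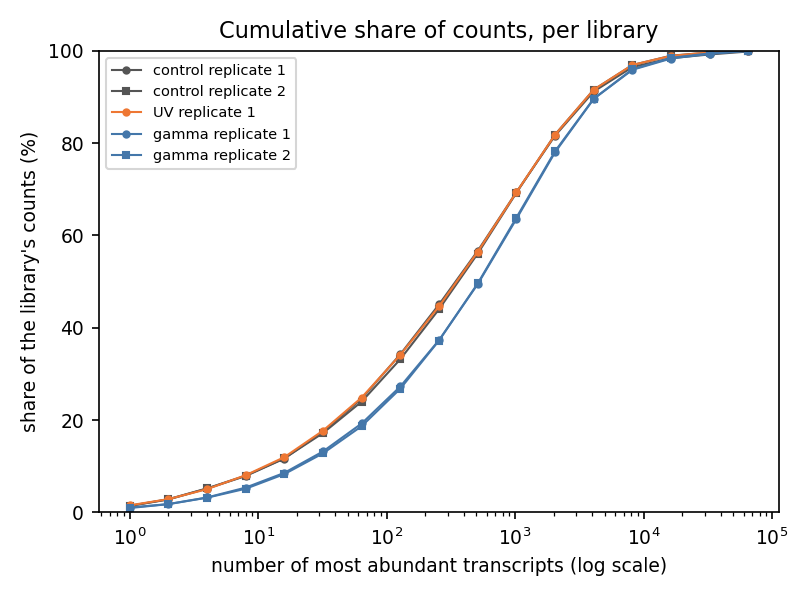
Share of a library's counts (y axis, %) held by its most abundant transcripts, against their number (x axis, log scale); one line per library, coloured by group. The UV library lies on the control lines, and both gamma libraries run below them, with 24.0% of counts in the top 100 transcripts against 30.1% in controls.

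Gamma irradiation was compared with no irradiation to find the transcripts that differ 24 h later. Of 27711 transcripts, 3787 changed: 2076 rose, with a median log2 fold change of 2.23, and 1711 fell, with a median of -1.28. Of these, 1828 rose and 1184 fell by an estimated 2-fold or more. The transcripts that rose took 4.22% and 4.34% of counts in the control libraries and 13.0% and 14.1% in the gamma libraries. Those that fell took 41.7% and 42.4% in controls and 26.7% and 27.1% after gamma. The calls came from 2926 loci. The balance of rises and falls was not stable: with library totals alone, which shifted the median log2 fold change of all transcripts by 0.24, 2950 rose and 1073 fell, and without gamma replicate 2 it turned, with 47.6% of 4248 calls higher against 54.8% of 3787. With a filter of at least 10 CPM in 2 libraries, 2137 of the 7339 transcripts left were called. Of the 3787 calls, 2190 were among those left, and 1955 of these were kept.

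The direction of the gamma change differed between abundance classes. Among the 142 transcripts above 10 log2 CPM, 81 fell, 3 rose and 58 did not pass the test, and the median log2 fold change was -0.45. These 142 held 35.7% and 34.5% of counts in controls, 35.3% in the UV library, and 28.0% and 27.5% after gamma. Among the 636 transcripts of 8 to 10 log2 CPM, 180 fell and 71 rose. Among the 3001 of 4 to 6 log2 CPM, 429 fell and 416 rose with TMM scaling, which itself centres the bulk of transcripts. Among the 7588 of 0 to 2 log2 CPM, 684 rose and 255 fell. Of the 10 transcripts with the highest mean level (4501 to 13102 CPM), 9 fell and 1 did not pass, at a log2 fold change of 0.15. The classes were set after the data were seen. The number that fell among the 142 was 47 both with library totals alone and without control replicate 1, and it was 59 to 94 with RLE or upper quartile scaling, DESeq2 or another library left out.

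**Figure D2:**
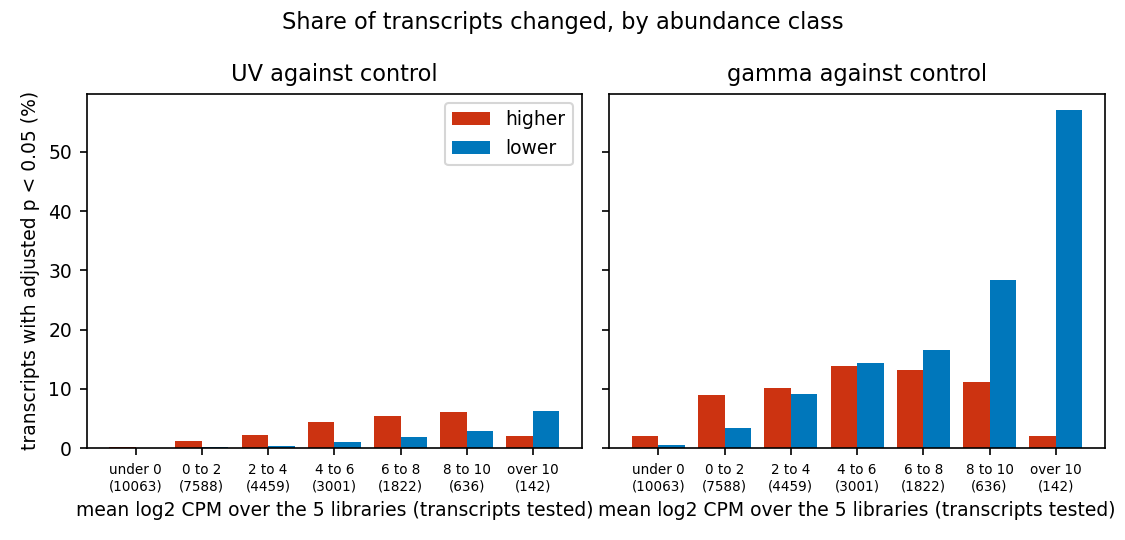
Share of tested transcripts (y axis, %) past an adjusted p of 0.05 in edgeR's quasi-likelihood test, higher in red and lower in blue, by mean log2 CPM over the 5 libraries (x axis, transcripts tested in brackets). Under gamma, 57.0% of the transcripts above 10 log2 CPM were lower and 2.11% higher; under UV, 6.34% were lower and 2.11% higher.

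TRINITY_DN202_c4_g1_i2 had 0 counts in both controls and 35.1 ± 11 CPM after gamma (SD, n = 2), at least 179-fold higher against a floor of 3 counts per library (edgeR quasi-likelihood test, adjusted p = 1.2e-09). TRINITY_DN313_c1_g1_i8 had 2 counts over both controls and 1215 over both gamma libraries, a ratio of 622 with an exact 95% interval of 172 to 5140 (adjusted p = 7.35e-09 in edgeR). Both of the control counts came from control replicate 2, and the log2 fold change was 9.08. It was 8.02 without control replicate 1, 9.57 without gamma replicate 1 and 8.34 without gamma replicate 2. Without control replicate 2 the remaining control had 0 counts, and the level after gamma was at least 222-fold higher than its floor of 3 counts. The sum over the 8 transcripts of its locus did not pass the test (log2 fold change 0.51 ± 0.20 SE, adjusted p = 0.108 in edgeR), whereas that of the 3 transcripts of the TRINITY_DN202_c4_g1 locus did (9.21 ± 0.45 SE, adjusted p = 3.68e-10 in edgeR). TRINITY_DN325_c3_g1_i2 fell 21-fold, from 356 ± 7.3 to 17.0 ± 4.5 CPM (SD, n = 2 each), with a log2 fold change of -4.39 ± 0.23 SE (adjusted p = 1.08e-10 in edgeR), and its locus also fell (-2.84 ± 0.18 SE). TRINITY_DN700_c0_g2_i10 was estimated at a log2 fold change of -4.69 ± 0.855 SE (adjusted p = 6.85e-04 in edgeR), but it had 43 counts in control replicate 1 and 842 in control replicate 2. Without control replicate 2 its log2 fold change was -1.14 and did not pass the test, without control replicate 1 it was -5.66, and its locus of 13 transcripts did not pass (-0.29 ± 0.16 SE).

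UV irradiation was compared with the same controls. In the single UV library, 615 transcripts passed the test: 485 were higher, with a median log2 fold change of 1.99, and 130 were lower, with a median of -1.51. The higher transcripts took 2.86% and 2.76% of counts in controls and 6.25% in the UV library, and the lower ones 3.84% and 4.30% in controls and 2.06% in the UV library. Among the 142 transcripts above 10 log2 CPM, 9 were lower and 3 higher, and the median log2 fold change was 0.04. Among the 3001 of 4 to 6 log2 CPM, 134 were higher and 30 lower. UV has no replicate check, and these calls assume that its library varies as the control and gamma libraries do. Their number was 234 with at least 10 CPM in 2 libraries (202 higher, 32 lower), 313 with a filter for 2 libraries (273 and 40), 340 with edgeR's newer method (288 and 52), 1679 with UV and control alone (1002 and 677), 1717 without gamma replicate 1 (1050 and 667) and 1733 without gamma replicate 2 (1076 and 657).

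TRINITY_DN2147_c0_g1_i3 had 11 and 2 counts in the controls and 1645 in the UV library, a log2 fold change of 8.38 ± 1.35 SE (edgeR quasi-likelihood test, adjusted p = 0.00106), 9.87 without control replicate 1 and 7.71 without control replicate 2. It did not pass with at least 10 CPM in 2 libraries or with the filter for 2 libraries. The gamma libraries had 1787 and 17 counts of it, and the sum over its locus of 3 transcripts did not differ between UV and control (log2 fold change 0.12 ± 0.15 SE, adjusted p = 0.817 in edgeR). TRINITY_DN202_c4_g1_i2 was also named here, with 16 counts in the UV library, at least 7.04-fold higher than the control floor (adjusted p = 7.47e-04 in edgeR), and it did not pass with edgeR's newer method. TRINITY_DN325_c3_g1_i2 was lower, at 19.7 CPM in the UV library (log2 fold change -4.18 ± 0.30 SE, adjusted p = 5.91e-08 in edgeR). TRINITY_DN917_c0_g1_i4 was 14.2-fold lower, from 21.0 ± 8.4 CPM in controls (SD, n = 2) to 1.46 CPM (adjusted p = 7.11e-04 in edgeR), and it had 1.94 ± 1.0 CPM after gamma (SD, n = 2). Its locus of 8 transcripts was lower too (-3.31 ± 0.48 SE). The place of TRINITY_DN202_c4_g1_i2 among the 2 largest rises under UV rests on a fitted fold change that depends on the prior count. It met the minimum of 3 log2 CPM through the gamma libraries, as it had 1.38 CPM in the UV library.

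Most transcripts that passed under UV also passed under gamma in the same direction. Of the 615 UV calls, 347 were higher in both and 104 lower in both, which is 73.3% of the UV calls and 11.9% of the gamma calls. Independent lists would share 36 and 8. Simulated unchanged groups against shared controls had at most 3 calls per comparison, too few for a chance level of shared calls. At an unadjusted p under 0.05 in both, 1858 transcripts went the same way, against a median of 201 (173 to 231) in 20 such sets. These sets hold no changed transcripts, whereas in the data 3432 transcripts for UV and 6859 for gamma had such a p. The 201 is therefore not a chance level for sharing between lists of that size. The UV and gamma differences in mean log2 CPM from control had a covariance of 0.469 across transcripts, against 0.185 (0.178 to 0.192) in those sets, a difference of 0.284. Their correlation was 0.438 against 0.398. With 1 control library for each comparison, the covariance was 0.226 and 0.291 for the 2 ways to assign them, and at most 0.00958 in the simulated sets. The counts of shared calls use both controls in each comparison, so part of their excess may come from these. Shared calls numbered 235 at an adjusted p under 0.01 in edgeR, 915 without gamma replicate 1 (53.3% of the UV and 24.6% of the gamma calls) and 1103 without gamma replicate 2 (63.6% and 26%). To keep the selection apart from the comparison, gamma calls were made with 1 control library and the UV library was set against the other. The UV library then lay above that control for 1228 of 1704 (72.1%) and 1232 of 1699 (72.5%) transcripts that rose under gamma. It lay below that control for 995 of 1316 (75.6%) and 963 of 1290 (74.7%) that fell. On average, 50% would follow if the UV library were exchangeable with a control library. With 1 UV library, a departure can also come from any other difference of that library, and transcripts are not independent replicates.

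**Figure D3:**
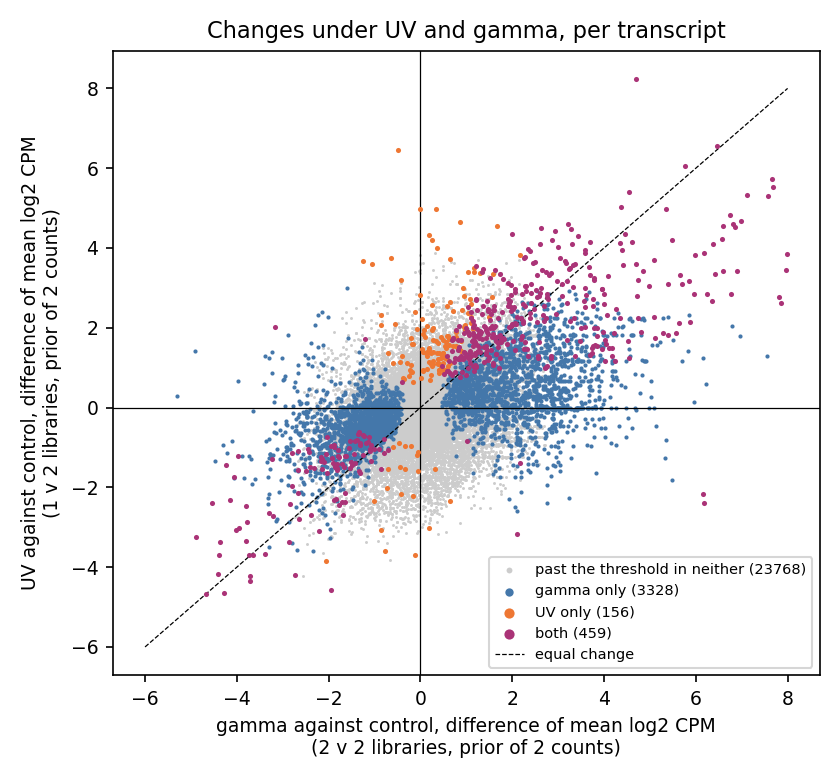
Difference of mean log2 CPM from control (prior of 2 counts) per transcript under gamma (x axis) and UV (y axis), coloured by which comparison passed an adjusted p of 0.05 in edgeR; the dashed line marks equal change. The 459 transcripts past the threshold in both lie mostly in the lower left and upper right quadrants, and 8 of them lie in the other two.

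UV and gamma were also compared directly, since a transcript that passes in one comparison only need not differ between them. This comparison called 1452 transcripts, of which 690 were higher and 762 lower in the UV library than in the gamma libraries. With library totals alone, which shifted the median log2 fold change by -0.27, 353 were higher and 1106 lower, and without gamma replicate 2 the balance turned, with 1194 higher and 845 lower. Of the 3328 transcripts that passed under gamma and not under UV, 1005 differed between the irradiations, and for the others a difference was not shown. Of the 156 that passed under UV and not under gamma, 87 differed. Of the 347 higher in both, 73 were higher after gamma than after UV and 26 were higher after UV. Of the 104 lower in both, 18 were lower after gamma than after UV. Among the 142 transcripts above 10 log2 CPM, 64 were higher in the UV library than in the gamma libraries and the other 78 did not pass. The number of calls was 742 with at least 10 CPM in 2 libraries, 930 with a filter for 2 libraries and 2286 without gamma replicate 1.

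TRINITY_DN1503_c0_g1_i4 had 40.2 CPM in the UV library, 0.331 ± 0.13 in controls and 0.197 ± 0.086 after gamma (SD, n = 2 each), a log2 fold change of 7.60 ± 0.52 SE between UV and gamma (edgeR quasi-likelihood test, adjusted p = 9.05e-08). Its locus of 4 transcripts also differed (4.19 ± 0.39 SE). Filters for at least 10 CPM in 2 libraries or for 2 libraries removed this transcript, so its test rests on the counts of the single UV library. TRINITY_DN88_c7_g1_i1, the single transcript of its locus, went opposite ways. It rose from 48.7 ± 0.38 CPM in controls to 198 CPM in the UV library (log2 fold change 2.02 ± 0.25 SE, adjusted p = 4.9e-05 in edgeR) and fell to 5.35 ± 0.90 CPM after gamma (-3.19 ± 0.24 SE, adjusted p = 1.21e-08 in edgeR). TRINITY_DN1111_c0_g1_i8 had 0 counts in the UV library and 22.1 ± 8.4 CPM after gamma (SD, n = 2), at least 85.8-fold higher after gamma against a floor of 3 counts (adjusted p = 3.74e-06 in edgeR). TRINITY_DN1111_c0_g1_i6, of the same locus of 7 transcripts, had 2.8 ± 2.1 CPM in controls, 0.344 CPM in the UV library and 190 ± 70 CPM after gamma (SD, n = 2), and it differed between the irradiations by a log2 fold change of -9.08 ± 0.70 SE (adjusted p = 4.16e-07 in edgeR). The locus summed over its transcripts rose under gamma (5.94 ± 0.35 SE) and was at -1.95 ± 0.56 SE under UV, with an adjusted p of 0.0849 in edgeR.

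**Figure D4:**
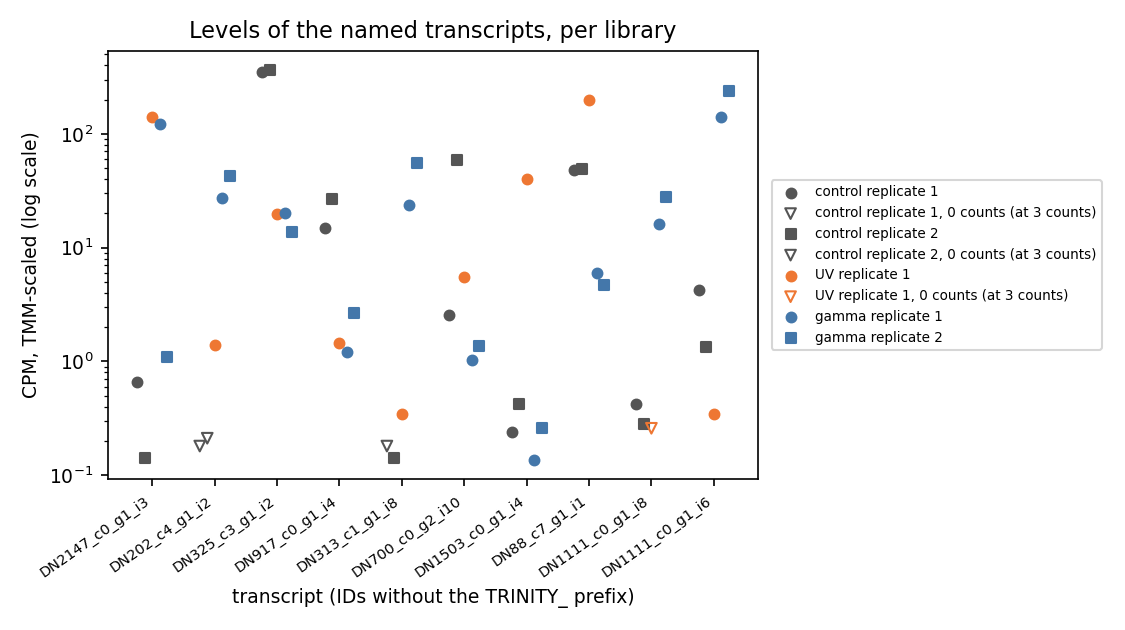
TMM-scaled CPM (y axis, log scale) of each named transcript in each of the 5 libraries (x axis, transcript), coloured by group; open triangles mark libraries with 0 counts, drawn at the level of 3 counts. TRINITY_DN88_c7_g1_i1 stands at 198 CPM in the UV library and at 5.98 and 4.71 CPM in the gamma libraries, on either side of the controls.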

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

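The test of mixing as the cause of the falls and the values with separate controls were chosen after the result was seen. The tests of shared controls and of mixing in strongly raised transcripts were written down before their results.

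The effects of UV and gamma against the same controls differed for 1452 transcripts in edgeR's direct comparison. For 8 transcripts the effects passed the threshold in opposite directions and also differed: 3 were higher under UV and lower under gamma, and 5 the reverse. TRINITY_DN88_c7_g1_i1 and TRINITY_DN1111_c0_g1_i6 are among them, and the UV side of each rests on 1 library.

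The UV library had moved towards gamma for 72.1% to 75.6% of gamma calls when a separate control was used for either, and over all 27711 transcripts the covariance of the UV and gamma differences from control was 0.469, against at most 0.192 in unchanged groups, and 0.226 and 0.291 with separate controls, so shared control libraries alone do not account for it. Gamma RNA or reads mixed into the UV library would give one linear share of the gamma change, and the median share was 17.6% for the 2076 rises (quartiles 1.37% and 53.3%) and 52.1% for the 1711 falls (quartiles 21.7% and 74.9%). Mixing at 21.7%, the lower quartile of the falls, would also keep the UV level above 21.7% of the gamma level. For 193 rises the upper 95% counting limit in UV lay under that share of the lower gamma library, against 11 between the gamma libraries in either order. These counts cannot decide on mixing as the cause of the falls. Mixing would place the UV level of some rises close to that share, where spread beyond counting error can carry it under. The gamma libraries are replicates at similar levels, so few of their transcripts come near it. The 145 transcripts called at least 8-fold higher under gamma, with a mean of at least 3 log2 CPM, had a median share of 7.83% (quartiles 3.81% and 17.8%). In 12 of them the UV level lay at or below the control mean. For the 145, mixing at a small share cannot be told apart. Their spread around the gamma level was 1.76 times that between the gamma libraries, between the bounds set for either reading. A response to UV that overlaps with that to gamma may also explain the pattern, and it was not tested, since UV has 1 library.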

How the results depend on the processing

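The newer quasi-likelihood method, library totals, the filter for 2 libraries and locus sums were chosen after the data were seen, as were all settings for the most abundant class and, for named transcripts, upper quartile scaling, the filters and the 2-group fits. The number of UV calls moved most. Against 615, it was 234 with at least 10 CPM in 2 libraries, 313 with the filter for 2 libraries, 340 with the newer quasi-likelihood method, 1679 with only the 2 groups compared, and 621 to 1733 with a library left out (1717 and 1733 without gamma replicates 1 and 2). The prior degrees of freedom, 16.8 in the reported fit, were 5.06 and 7.6 under the 2 filters and infinite without a filter and in the fits with 1 residual degree of freedom (UV with control or gamma alone, the block, and any control or gamma library left out), where p-values rest on the abundance trend alone. Gamma calls were 2137 with at least 10 CPM, and otherwise stayed within 1.5 times of 3787. Similar totals need not hold the same transcripts: of the 3787 gamma calls, RLE scaling kept 3730 and DESeq2 kept 2874. With a control library left out, part of the UV and gamma calls was also exchanged for others. Calls between UV and gamma were 742 with at least 10 CPM, 930 with the filter for 2 libraries, and 1780 to 2286 with a control or gamma library left out (2286 without gamma replicate 1). Calls shared by both irradiations were 235 at an adjusted p under 0.01, and 427 to 1103 with a library left out (915 and 1103 without gamma replicates 1 and 2). The most abundant transcripts lower under gamma numbered 47 with library totals alone and 47 (without control replicate 1) to 94 with a library left out. Replicate numbers did not pair the samples (the differences between replicates 1 and 2 of control and gamma correlated at r = 0.028 across 27711 transcripts), and with them as a replicate block 827 (612 higher, 215 lower), 4337 and 1722 transcripts (913 higher, 809 lower) were called for UV, gamma and UV against gamma. The cause of the other moves was not tested. No named transcript reversed: of 169 values under these settings, 165 passed in the same direction and 4 did not pass (TRINITY_DN700_c0_g2_i10 without control replicate 2; under UV, TRINITY_DN2147_c0_g1_i3 with either stricter filter and TRINITY_DN202_c4_g1_i2 with the newer method). Of 10 sums over their loci of 2 or more transcripts, 7 passed in the same direction and 3 did not pass. Comparisons with UV give no value without its library. The filter of at least 10 CPM removed TRINITY_DN1503_c0_g1_i4 and TRINITY_DN700_c0_g2_i10, and the filter for 2 libraries removed TRINITY_DN1503_c0_g1_i4. Those cases gave no value and are not among the 169. The named transcripts were picked from these same data for large changes with the groups apart. A reversal was therefore unlikely from the start, and the 165 are not independent support. The gene list tests were not run for lack of names. On simulated data with 200 changed transcripts, 2-fold changes were mostly missed, with 5 of 50 recovered for gamma and 1 of 50 for UV. More transcripts were called in the data (3787 for gamma, 615 for UV), which makes the adjusted threshold less strict. The recovered shares therefore hold for the simulated setting only.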

Other observations

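The tests on the most abundant transcripts were chosen after the result was seen. The ratio for loci of several transcripts was written down before its result, and its exact test was chosen after.

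Some transcripts were found on one side only. There were 197 transcripts with 0 counts in both controls and at least 20 counts over the gamma libraries, 195 of them in both gamma libraries, and 67 with 0 counts in both gamma libraries and at least 20 over the controls. Pairs that mix the groups gave 11 to 46 such transcripts. Of the 197, 131 passed the test under gamma, and 111 had at least 1 count in the UV library, 20 of them at least 10. Control replicate 1 held 83156 transcripts with a count, against 58778 in control replicate 2, and 79058 against 57511 after thinning to 12707113 counts. It alone held 13244 of them, with a median of 4 counts and 0.29% of its counts in all.

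Scaling between libraries alone does not account for the fall of the most abundant transcripts under gamma, though their number fell from 81 to 47 with library totals alone. The median log2 fold change above 10 log2 CPM was 0.38 below that of 4 to 6 log2 CPM (difference -0.38), a difference that a scaling factor leaves unchanged. Its interval of -0.48 to -0.33 came from resampling transcripts and not libraries, so it holds no spread between libraries. Under UV the difference was 0.04. Lowering of all abundant transcripts by 1 factor stays open: the SD of their fold changes was 3.56 times the median standard error, with 25 of 142 at least 2-fold lower and 14 above 0, but it was also 2.31 times under UV, where the class median did not shift, so changes of single transcripts on top of a common one cannot be told apart. An effect of gamma irradiation and an unlabelled difference in handling between the control and gamma samples may both explain the pattern, and the design does not separate them.

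Part of the calls in loci of several transcripts was not seen in the sum over the locus. Under gamma, 2000 of 2447 calls (81.7%) in loci of 2 or more transcripts had a locus call in the same direction, 415 had none and 32 had one in the opposite direction, and under UV 221 of 334 (66.2%) had one in the same direction. In loci of 1 transcript, where nothing is summed, it was 1294 of 1340 calls (96.6%) under gamma and 271 of 281 (96.4%) under UV. Some calls were thus lost through the separate fit of the loci alone. Of 520 loci with 2 or more gamma calls, 48 were called both ways. Reads shared between near-identical transcripts of a locus are a candidate explanation, examined above 3 log2 CPM at matched abundance. There, 4-fold differences between the control libraries were 6.73 times as frequent in loci of 2 or more tested transcripts as in loci of 1. The shares were 0.404% and 0.06% (exact test stratified by abundance, two-sided, p = 0.0054). Between the gamma libraries the ratio was 2.35 (0.539% and 0.229%, p = 0.035 in the same exact test). Such transcripts are few (19 against 2 between the controls, 24 against 6 between the gamma libraries). The exact test counts transcripts of one locus as independent, which they are not, so its p-values may be too small. A change in isoform use under irradiation remains open.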
